A study of Homo sapiens with 9 samples.

How the data were processed

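Total RNA of 9 samples, labelled as the human neuroblastoma line SH-SY5Y, was measured on arrays, 3 each for untreated cells and for cells exposed for 12 h to 20 nM or 60 nM OA. Per the labels' protocols the RNA was column-purified and biotin-labelled cRNA was made by in vitro transcription. The authors deposited 1 table of 70523 probe sets with a value per array. The submitters' processing notes name RMA (background correction, normalization and probe summary across arrays). Its version, the annotation and the genome build are not given in the sources used here. The deposited values are intensities on a linear scale, with a median of 21.8 and a highest value of 999953, and not the log2 values that RMA usually gives and that the test plan had assumed. Whether a further transformation was applied stays unknown. The values were therefore set on a log2 scale with no added constant. Such processing makes the distributions of the arrays alike, so that a shift common to most genes would not be seen. The median log2 value of the arrays lay between 4.36 and 4.51. Values repeat: 12364 of 22465 genes had 3 or more of the 9 arrays at 1 value to 4 decimals. This can make the SE of such genes too small. Bright genes show repeats as well as dim ones, such as HEXIM1 at 10.496 on all 3 arrays at 20 nM.

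Probe sets were named through the platform annotation: 23781 had 1 gene symbol, 1543 had several and 42204 transcript clusters had none listed, while 2995 were control or exon-level sets. Probe sets with several symbols or none were left out of the comparisons. For 479 genes with several probe sets the one with the highest mean over the 9 arrays was used, which gave 22465 genes. Of these, 20295 were found by gene number in a RefSeq gene table of the human assembly GRCh38.p14, which changed 0 symbols. That table was used for names alone, and since no build is named for the arrays no coordinates are given. The 95th percentile of 23 background probe sets over all arrays, 5.82, served as the background level, and 10062 genes had a group mean above it.

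All 9 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend) with a term per group, so that the 3 groups share 1 estimate of spread. The 3 pairwise contrasts were tested with the Benjamini-Hochberg adjusted p under 0.05 as the threshold, and the 3 groups together by limma's F test. Gene lists (32, fixed before the data were examined) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Named genes were chosen by a rule set before the data were examined: for each dose against untreated cells the 10 that rose and the 10 that fell most, and for 60 nM against 20 nM the 5 and 5, among called genes whose groups of 3 arrays did not overlap and whose higher mean exceeded the median of all values, up to 4 members of each list by smallest p, and always PPP2CA, PPP2CB, PPP1CA, MAPT, FOS, EGR1 and CDKN1A. The result of 1 gene that the rule takes is not reported here. Genes called at both doses were set beside 50 simulated sets of unchanged arrays. Figures were drawn with matplotlib 3.10.9.

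The functions were tested on simulated arrays with the real means and spreads of the 22465 genes and 50 changed genes at each fold size per contrast. The changed genes were drawn from those with a mean above the median of all values, and the noise was independent between genes and arrays. The rates therefore do not cover dimmer genes or variation that genes share. For 60 nM against untreated, 78% of genes changed 1.5-fold, 92% changed 2-fold and 98% changed 4-fold were called. For 20 nM against untreated the values were 74%, 88% and 98%, and for 60 nM against 20 nM 74%, 84% and 100%. Of genes changed by the smallest simulated size, 0.32 on the log2 scale, 36%, 50% and 48% were called in these contrasts. Between 7 and 13 unchanged genes were called.

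Array quality was planned as the difference between 3 prime and 5 prime control probe sets, but the table holds no such pairs for GAPDH or ACTB. The spiked controls were compared in their place by exact two-sided permutation tests, which with 3 against 3 arrays cannot give a p under 0.1. The mean of the hybridisation controls was 9.71 ± 0.17 (SD, n = 3) untreated, 9.42 ± 0.23 at 20 nM and 9.70 ± 0.25 at 60 nM (exact p = 0.3 and 1 against untreated), and that of the poly-A controls 6.94 ± 0.24, 6.78 ± 0.27 and 6.68 ± 0.25 (exact p = 0.5 and 0.4). The array medians (log2) were 4.430 ± 0.005 untreated and 4.472 ± 0.032 at 60 nM and did not overlap (exact p = 0.1, the smallest possible). Within groups the arrays correlated across genes at 0.995 or higher, with untreated replicate 3 and 20 nM replicate 2 farthest from the others of their groups. The files give no scan date or batch. The labels call the arrays biological replicates without saying whether they came from separate cultures, so p-values measure the spread between these samples.

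Alternatives were each gene's probe sets tested singly or averaged, dim genes left out, quantile normalization, cyclic loess, a shift by the hybridisation controls, a trended and robust variance, array weights (whose estimation did not converge), fits of 6 arrays, the replicate number as a block, stricter thresholds, and each array left out in turn. Added after seeing the data were the removal of genes with repeated values, the removal of 2 arrays that stand apart, equal array medians, and a chromosome score of each array as a covariate. The score is the median of genes above background on chromosomes 16, 17, 19 and 22 minus that on chromosomes 4, 5, 13 and 18, with the chromosome read from the probe set name.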

Results

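RNA from cells labelled SH-SY5Y was hybridised to 9 arrays. SH-SY5Y is a human neuroblastoma line that is widely used as a model of noradrenergic neurons. The cells had been left untreated or exposed for 12 h to okadaic acid (OA) at 20 nM or 60 nM, with 3 arrays per group that the labels call biological replicates. OA is a marine toxin that inhibits serine/threonine phosphatases of the PP1 and PP2A type. The labels of the 60 nM arrays disagree among themselves: the title code, the source name and the series design give 60 nM, while the treatment field gives 20 nM, and the arrays were grouped as 60 nM. The comparisons asked which transcripts each dose changed and how the doses differed. The number of arrays limits the precision of every value. Values are log2 intensities, with mean ± SD of 3 arrays, and fold changes are log2 differences with their standard error (SE). The first principal component held 72.6% of the variance and set the 60 nM arrays (scores 36.8, 36.8 and 37.5) apart from the other 6 (scores of -29.8 to -12.4).

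In untreated arrays, the genes of the cell cycle were bright while most markers of noradrenergic neuroblastoma were not above background, taken as 5.82, the 95th percentile of 23 background probe sets. All 33 measured DNA replication genes and all 35 mitosis genes had an untreated mean above that level. Of 25 noradrenergic identity genes 6 did, among them HEY1 (9.30 ± 0.06, n = 3), HAND1 (8.66 ± 0.20), GATA2 (7.76 ± 0.10) and GATA3 (7.33 ± 0.06). TH, the rate-limiting enzyme of catecholamine synthesis (4.57 ± 0.01), DBH, which makes noradrenaline (4.22 ± 0.02), PHOX2A, a transcription factor of noradrenergic neurons (3.49 ± 0.08), and CHGA, a protein of secretory granules (4.14 ± 0.00), were at background. MAPT, which encodes tau, was at background too (4.86 ± 0.06). Above background were 10 of 26 neuronal cytoskeleton genes, 4 of 27 synaptic vesicle genes, 12 of 22 mesenchymal type neuroblastoma markers, 4 of 16 epithelial markers, 1 of 15 leukocyte markers and 0 of 11 Schwann and glial markers. VIM (11.51 ± 0.08) and CD44 (10.48 ± 0.09) of the mesenchymal list and the keratins KRT8 (13.34 ± 0.20) and KRT18 (12.56 ± 0.20) of the epithelial list were bright. Of these genes, HAND1, GATA2, TH, DBH, PHOX2A, CHGA, VIM and KRT8 were named after their values were seen.

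**Figure D1:**
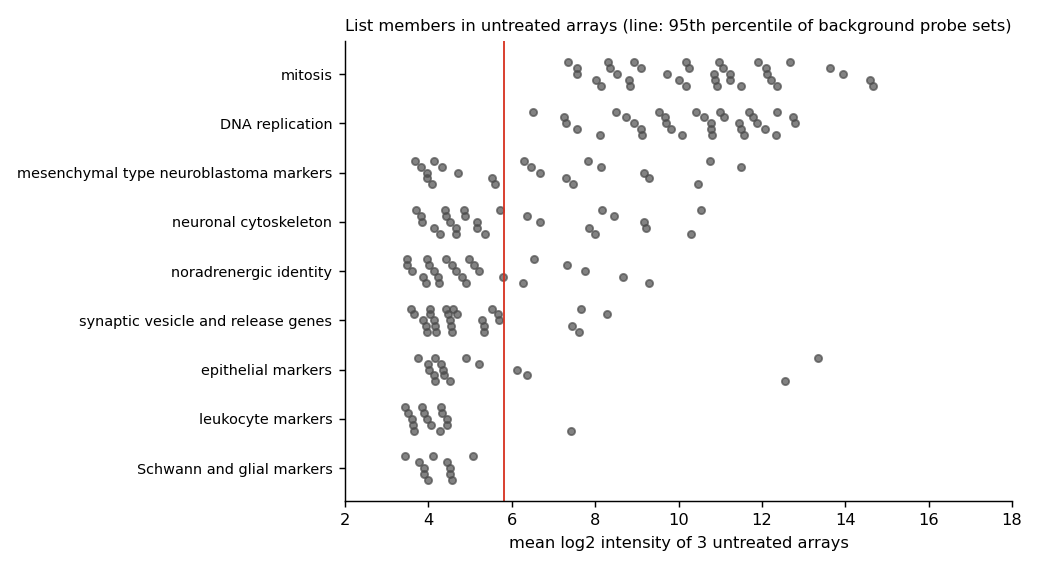
Mean log2 intensity over the 3 untreated arrays (horizontal axis) of each measured member (point) of 9 gene lists (rows), with a line at 5.82, the 95th percentile of the background probe sets. All mitosis and DNA replication genes lie to the right of the line, and 6 of 25 noradrenergic identity genes do.

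At 60 nM OA, most of the measured immediate early genes, feedback inhibitors of MAP kinase signalling and mitosis genes rose against untreated cells, while most DNA replication genes fell. The genes that rose most were ACTBL2, an actin-like gene (6.86 ± 0.18 to 13.32 ± 0.43, log2 fold change 6.46, SE 0.36, limma adjusted p = 4.14e-05), ATP1B2, a sodium pump subunit (5.15, SE 0.15), CCDC80 (5.03, SE 0.11), JUNB, an AP-1 transcription factor (5.02, SE 0.20), and GABRQ, a GABA receptor subunit (5.00, SE 0.13). They were followed by the transcriptional repressor SNAI1 (4.42), TENT5C (4.28), RFPL4AL1 (4.24), the EGF receptor ligand HBEGF (4.13) and the cytokine TNFSF9 (4.08). The untreated means of ATP1B2, CCDC80, JUNB, GABRQ, SNAI1, TENT5C and RFPL4AL1 were at background, so that their folds depend on the background level. The genes that fell most were TMEM150C (log2 fold change -2.54, SE 0.06, adjusted p = 1.96e-06), DHX32 (-2.50, SE 0.10), MIR3198-1 (-2.40, SE 0.30), ANKRD1, a target of the coactivator YAP (-2.31, SE 0.36), and LOC100129034 (-2.22, SE 0.23). The fold of LOC100129034 depends on the background level, where its mean at 60 nM lay. MMD (-2.16), BTBD2 (-2.15), the nuclear pore gene NUP210 (-2.14) and the cold-inducible RNA-binding protein gene CIRBP (-2.11) were also among the 10 largest falls. The 3 arrays of the 2 groups did not overlap for any of these genes, by the rule that chose them.

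Of 28 immediate early genes, which are transcribed within minutes to hours of a stimulus, 24 rose at 60 nM and 1 fell, both over all genes tested and adjusted over the list alone. JUNB led the list, with ARC (3.32, SE 0.14), NR4A2 (2.00, SE 0.10), FOS (1.89, SE 0.11), EGR1 (1.82, SE 0.24) and NR4A3 (1.49, SE 0.04) among the others, and CCN1 fell by 0.53 (SE 0.13). The CCN1 call was lost without untreated replicate 2 (adjusted p = 0.0791) or 3 (0.0610) or any 1 of the 60 nM arrays (0.0532 to 0.0849), and in the fit of 6 arrays (0.0663). Of the 24 that rose, 12 had an untreated mean at background, FOS among them, so that their folds depend on the background level, and 6 of these, NR4A3 included, were still at background at 60 nM. Of 18 genes listed as feedback inhibitors of MAP kinase signalling 13 rose (14 adjusted over the list alone) and none fell. They included ERRFI1, an inhibitor of the EGF receptor (2.84, SE 0.07), the phosphatase DUSP10 (1.62, SE 0.12) and SPRY4, which went from 5.47 ± 0.09 to 6.72 ± 0.09. IER3 (2.19, SE 0.19) rose too and is counted with the list, but it is not taken here as an inhibitor. The untreated means of DUSP10 and SPRY4 were at background, as were those of 5 of the 13 that rose. The camera test with a preset correlation of 0.01 called both lists higher (adjusted p = 1.51e-16 and 1.30e-09), and adjusted p = 0.242 with an estimated correlation ended both calls.

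The 2 cell cycle lists moved in opposite directions at 60 nM. Of 35 mitosis genes 27 rose (29 adjusted over the list alone) and none fell, with KIF20A, a mitotic kinesin (1.14, SE 0.10), PTTG1, or securin (0.96, SE 0.04), AURKA, a mitotic kinase (0.84, SE 0.07), and CCNA2, or cyclin A2 (0.81, SE 0.05), having the smallest p. Of 33 DNA replication genes 25 fell (26 adjusted over the list alone). The members of smallest p were PRIM1, the small primase subunit (-2.00, SE 0.08), the replicative helicase subunits MCM6 (-1.79, SE 0.10) and MCM5 (-1.59, SE 0.08), and the clamp loader subunit RFC4 (-1.22, SE 0.06). Another helicase subunit gene, MCM3, fell by 2.00 (SE 0.12). The 3 that rose, named after their values were seen, were the cyclin E genes CCNE2 (1.34, SE 0.18) and CCNE1 (0.88, SE 0.12) and the ribonucleotide reductase subunit RRM2 (0.70, SE 0.06). Camera called mitosis higher (adjusted p = 5.60e-14) and DNA replication lower (6.69e-12), both lost at adjusted p = 0.242 with an estimated correlation. Genes of both lists varied with a chromosome score of the arrays, the median of genes on gene-dense chromosomes minus that on gene-poor ones, which lay between -0.17 and -0.15 on the 60 nM arrays and between -0.04 and 0.32 on the untreated ones. With the score as a covariate, chosen after seeing the data, the list median was 0.37 in place of 0.71 for mitosis and -0.50 in place of -0.65 for DNA replication.

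**Figure D2:**
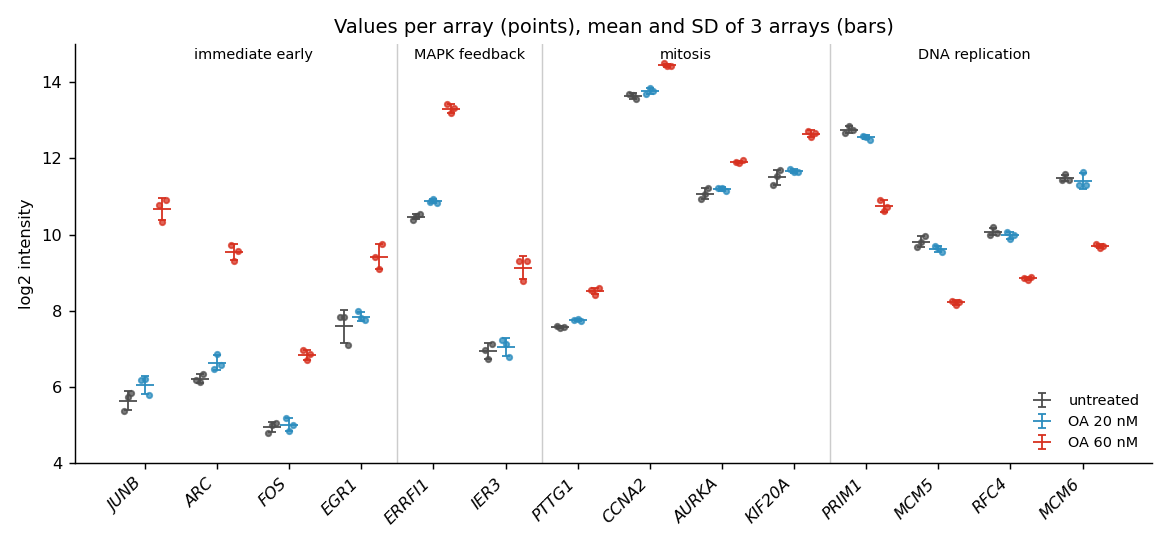
Log2 intensity (vertical axis) of 14 genes from 4 lists (horizontal axis) on each array (points), with the mean and SD of the 3 arrays of each group (bars), in untreated cells and at 20 nM and 60 nM OA. JUNB lies at 5.65 ± 0.25 untreated, 6.05 ± 0.24 at 20 nM and 10.67 ± 0.30 at 60 nM, and PRIM1 at 12.75 ± 0.10, 12.55 ± 0.05 and 10.75 ± 0.15.

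Of 37 oxidative phosphorylation genes 18 fell at 60 nM (25 adjusted over the list alone) and none rose, with the complex I genes NDUFS1 (-0.80, SE 0.04), NDUFB5 (-0.77, SE 0.06) and NDUFV1 (-0.74, SE 0.10) and the ATP synthase gene ATP5MC1 (-0.46, SE 0.05) having the smallest p. Of 27 cytosolic ribosomal protein genes 8 fell (11 adjusted over the list alone) and none rose, among them RPL10A (-0.55, SE 0.09), RPS16 (-0.45, SE 0.06), RPL11 (-0.22, SE 0.05) and RPL19 (-0.21, SE 0.04). All members of both lists were above background. On chromosome 1, which held the most genes above background, 279 of 972 such genes fell and 152 rose. The 8 of 27 ribosomal protein genes lower were thus near the share of such genes there. Camera called both lists lower (adjusted p = 1.87e-08 and 9.72e-05). With an estimated correlation the values were adjusted p = 0.379 and adjusted p = 0.534, and the calls ended. The ribosomal protein call was also lost after a shift by the hybridisation controls (adjusted p = 0.12), as were the calls of RPL10A, RPS16, RPL11 and RPL19. Their folds moved by 0.00867 under that shift, as did those of all genes, while limma gave every gene the same SE of 0.204. These 4 calls were lost with the chromosome score too, where RPL10A (-0.61) and RPL11 (-0.225) were no smaller than without it and RPS16 (-0.28) and RPL19 (-0.148) were, and RPL11 lost it without untreated replicate 2 (adjusted p = 0.0594).

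Stress and signalling lists held members that rose and members that fell. Of 28 hypoxia and glycolysis genes 12 rose and 3 fell (13 and 4 adjusted over the list alone), with the glucose transporter SLC2A3 (1.83, SE 0.09), EGLN3 (1.82, SE 0.06), the angiogenic factor VEGFA (1.34, SE 0.04) and BNIP3 (1.08, SE 0.04) having the smallest p. Of 23 p53 targets 9 rose and 3 fell (11 and 4 adjusted over the list alone), with PLK2 (2.88, SE 0.12), POLH (1.65, SE 0.09) and PLK3 (1.38, SE 0.08) higher, DDB2 lower (-2.01, SE 0.10), and CDKN1A, the cell cycle inhibitor p21, at 0.94 (SE 0.06). Of 19 heat shock genes 6 rose and 1 fell (7 and 1 adjusted over the list alone). DNAJB1 rose by 1.87 (SE 0.14), BAG3 by 0.98 (SE 0.12) and DNAJA1 by 0.57 (SE 0.06), and HSPB1 fell by 0.44 (SE 0.08). Of 21 NRF2 targets 8 rose and 1 fell, with the same counts adjusted over the list alone, including the glutathione synthesis genes GCLC (0.95, SE 0.07) and GCLM (0.41, SE 0.06), HMOX1 (0.83, SE 0.06) and TXNRD1 (0.59, SE 0.04). Of 24 ATF4 targets 8 rose and 6 fell (12 and 6 adjusted over the list alone), with CTH (1.33, SE 0.14), the amino acid transporter SLC7A5 (1.20, SE 0.11) and PPP1R15A (0.96, SE 0.08) higher and ALDH1L2 lower (-0.85, SE 0.07). Of 26 NF-kB targets and cytokines 5 rose and 2 fell, likewise adjusted over the list alone, with NFKBIZ at 1.57 (SE 0.08), TNFAIP3 at 0.99 (SE 0.11), and IL1A (0.44, SE 0.07) and PTGS2 (0.44, SE 0.04) still below the background level at 60 nM. Camera called these 6 lists higher, with adjusted p of 0.000218, 0.0191, 0.0302, 0.0191, 0.0373 and 0.0107 in the order given. None kept its call with an estimated correlation, where adjusted p = 0.518, 0.242, 0.242, 0.379, 0.534 and 0.534. For heat shock genes the estimate was 0.00356, below the preset 0.01, yet the unadjusted camera p went from 0.0113 to 0.0372. A higher correlation was thus not the reason for that loss, and the settings differ in more than the correlation. The untreated means of EGLN3, PLK3, HMOX1, PPP1R15A, IL1A and PTGS2 were at background, as was the mean of ALDH1L2 at 60 nM, so that their folds depend on it. A shift by the hybridisation controls ended the NF-kB (adjusted p = 0.133) and NRF2 (adjusted p = 0.0612) calls, and the chromosome score the p53 call (adjusted p = 0.0789). The heat shock call was lost without 60 nM replicate 1 (adjusted p = 0.0504). The ATF4 call was lost in the fit of 6 arrays (adjusted p = 0.0546) and without untreated replicate 1 (0.0665), untreated replicate 2 (0.0556) or genes with repeated values (0.259).

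Of 23 SRF and YAP cytoskeletal targets 7 fell and 3 rose at 60 nM (8 and 3 adjusted over the list alone). The tropomyosins TPM1 (-0.73, SE 0.07) and TPM4 (-0.42, SE 0.06) fell with ANKRD1, while THBS1 (0.51, SE 0.08, at background in untreated cells) and ZYX (0.49, SE 0.08) rose. The list's camera call (lower, adjusted p = 0.0373) was lost under 12 of the alternatives, with adjusted p from 0.00727 to 0.966 over all of them, 0.618 with an estimated correlation and 0.966 with the chromosome score.

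Of the neuronal lists a minority of members rose. Of 26 neuronal cytoskeleton genes 9 rose and 1 fell (10 and 1 adjusted over the list alone), with the tubulins TUBB2A (1.99, SE 0.13) and TUBA1A (0.56, SE 0.05), the neurofilament gene NEFL (1.92, SE 0.06) and the kinesin KIF5C (1.05, SE 0.10) having the smallest p, and 16 members were at background in untreated cells. Of 25 noradrenergic identity genes 7 rose and 1 fell, with the same counts adjusted over the list alone. GCH1, which makes the cofactor of tyrosine hydroxylase, rose by 3.18 (SE 0.05), RET (0.43, SE 0.05) and SOX11 (0.33, SE 0.05) rose at levels still at background, and GATA3 fell by 0.23 (SE 0.04). Camera called both lists higher (adjusted p = 0.000218 and 0.0401), lost at adjusted p = 0.242 and adjusted p = 0.534 with an estimated correlation. The noradrenergic call was lost under 9 alternatives, over which and all others adjusted p ranged from 0.00159 to 0.534.

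Among the PP1 and PP2A type phosphatase genes and the genes of tau and amyloid, 9 and 15 members changed at 60 nM with no call for either list (camera adjusted p = 0.840 and 0.886). Over all genes tested 21.2% were called, and of 972 genes above background on chromosome 1, 152 rose and 279 fell. Neither count is thus read as a response of its list. The tau and amyloid list had a median log2 fold change of 0.00 and a mean of -0.07. Of 37 PP1 and PP2A type phosphatase genes 3 rose and 6 fell (3 and 7 adjusted over the list alone). The PP2A catalytic subunit gene PPP2CB rose by 0.27 (SE 0.05). Its call was lost with quantile normalization (adjusted p = 0.0809), the hybridisation control shift (value 0.276, adjusted p = 0.791) and the fit of 6 arrays (0.0560). In the list, STRN4 (-0.63, SE 0.12), PPP5C (-0.47, SE 0.10) and IGBP1 (-0.42, SE 0.07) fell. The calls of STRN4 and PPP5C were lost in the fit of 6 arrays (adjusted p = 0.0501 and 0.0605) and without the 2 arrays that stand apart, untreated replicate 3 and 20 nM replicate 2 (0.0599 and 0.0514). PPP2CA (0.16, SE 0.08, adjusted p = 0.245) and PPP1CA (-0.20, SE 0.07, adjusted p = 0.103) did not pass the test. With equal array medians PPP1CA did (adjusted p = 0.0461), and PPP2CA had a value of -0.078 with the chromosome score. Of 30 tau and amyloid genes 6 rose and 9 fell (7 and 9 adjusted over the list alone), with the secretase genes NCSTN (-0.88, SE 0.09) and BACE1 (-0.84, SE 0.07) and the sorting receptor SORL1 (-0.67, SE 0.06, to a level at background) lower and the kinase FYN higher (0.40, SE 0.05). The fold change of MAPT was 0.03 (SE 0.03, adjusted p = 0.569), at background in all groups, and its sign turned under 2 other scalings.

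**Figure D3:**
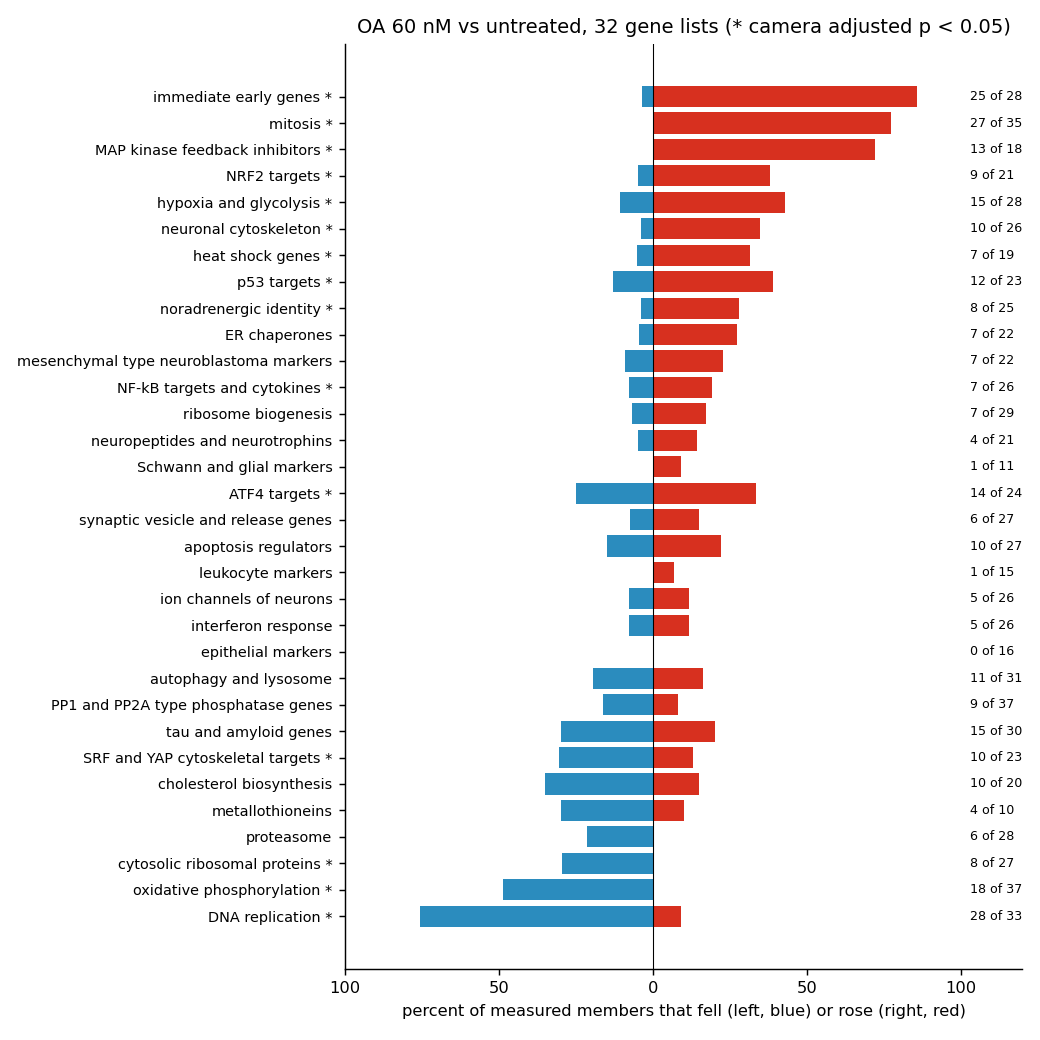
Percent of the measured members of 32 gene lists (rows) that rose (to the right) or fell (to the left) at 60 nM OA against untreated cells, with the number changed and measured at the right edge and an asterisk at camera adjusted p under 0.05. Immediate early genes (24 of 28), mitosis (27 of 35) and MAP kinase feedback inhibitors (13 of 18) lie at the top, and DNA replication (25 of 33 lower) at the bottom.

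In all, 4752 of 22465 genes differed between 60 nM OA and untreated cells (limma adjusted p under 0.05), 1783 higher and 2969 lower, and 472 and 297 of these changed at least 2-fold. Camera called 15 of the 32 lists, 11 higher and 4 lower, 0 with an estimated correlation, and fry, which tests whether a list moves on balance without setting it against other genes, called 22. The count of genes was 2533 with the chromosome score as a covariate. It was 2248 (1147 higher, 1101 lower) after a shift by the hybridisation controls. Of 128 called genes followed through the alternatives, 31 lost the call with that shift, among them ATP5MC1, CCN1, FYN, GATA3, GCLM, HSPB1, IGBP1, IL1A, PPP5C, PTGS2, RET, SOX11, THBS1, TPM4, TUBA1A and ZYX. The fold of each of the 31 moved by 0.00867, and these losses came with the SE, which went from between 0.025 and 0.128 to 0.204. With the chromosome score 26 lost the call, at a median SE of 0.0946 in place of 0.0757. Of these, 14 had a fold that shrank by over 1.5 times, among them CCN1 (-0.238), GATA3 (-0.135), HSPB1 (-0.206), IGBP1 (-0.25), PPP5C (-0.246), STRN4 (-0.337) and TPM4 (-0.272). The other 12 did not, among them ANKRD1 (-2.564, SE 0.625, adjusted p = 0.0511), EGR1 (1.27), GCLM (0.328), IL1A (0.41), NDUFV1 (-0.509) and SOX11 (0.228).

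At 20 nM OA, 5 genes differed from untreated cells by limma. HEXIM1, an inhibitor of the elongation factor P-TEFb, rose from 9.74 ± 0.05 to 10.50 ± 0.00 (log2 fold change 0.76, SE 0.05, adjusted p = 0.00744), SHISA2 rose by 0.77 (SE 0.07, adjusted p = 0.0393) and the ETS factor ETV1 by 0.28 (SE 0.02, adjusted p = 0.00744). FBXW8, a ubiquitin ligase subunit gene, fell by 0.53 (SE 0.04, adjusted p = 0.0366) and PBLD by 0.24 (SE 0.02, adjusted p = 0.00744), though the value of PBLD was 0.047 after a shift by the hybridisation controls. HEXIM1 and PBLD had the same value on all 3 arrays at 20 nM to the third decimal, and ETV1 and PBLD were below the background level. Such repeats can make an SE too small. With genes of repeated values left out, chosen after seeing the data, HEXIM1 and PBLD were not tested and ETV1 lost its call (adjusted p = 0.182). FBXW8 and SHISA2 kept theirs. At an unadjusted p under 0.05, 1119 of 22465 genes passed. That is near the share of 0.05 that would pass if no gene had changed, so it shows no excess. No gene was called without untreated replicate 1, untreated replicate 2, 20 nM replicate 1 or 20 nM replicate 3, and 19 were without untreated replicate 3. With equal array medians, chosen after seeing the data, all 5 calls were lost (adjusted p of 0.0577 to 0.368). In the fit of 6 arrays HEXIM1 kept its call (adjusted p = 0.0329) and the other 4 lost theirs (0.0721 to 0.101). The hybridisation control shift ended the calls of ETV1 (0.572) and FBXW8 (-0.236) beside that of PBLD, and quantile normalization those of FBXW8 (adjusted p = 0.0527) and PBLD (0.0578).

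No list had a member called over all genes at 20 nM, but camera called 11 of the 32 lists, 8 higher and 3 lower. MAP kinase feedback inhibitors were higher (adjusted p = 6.58e-06), with SPRY4 at 0.39 (SE 0.06) and ERRFI1 at 0.40 (SE 0.07) called adjusted over the list alone. With an estimated correlation, adjusted p = 0.725 ended this call. SRF and YAP cytoskeletal targets were lower (adjusted p = 3.04e-05), with AMOTL2 at -0.16 (SE 0.03, and 0.127 after the hybridisation control shift), CCN1 at -0.63 (SE 0.13) and CCN2 at -1.10 (SE 0.27) among the members of smallest p and 3 lower adjusted over the list alone. That call ended too, at adjusted p = 0.725 with an estimated correlation. Immediate early genes, heat shock genes, ER chaperones, ribosome biogenesis, NRF2 targets, the proteasome and hypoxia and glycolysis were higher, and DNA replication and metallothioneins lower, at adjusted p of 0.00117 to 0.0435. With an estimated correlation all 11 calls ended (smallest adjusted p = 0.243), and fry called 0. That smallest value was that of heat shock genes, whose estimated correlation of 0.00356 lay below the preset 0.01. Camera called 2 lists without 20 nM replicate 2 and 5 without untreated replicate 1.

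The 5 genes called at 20 nM changed in the same direction at 60 nM, where independent lists of these sizes would share 0.502. Unchanged groups simulated against the shared untreated arrays shared 0. No gene was changed at either dose in that simulation, so few calls and an overlap near 0 were set in advance. The lists are not independent either, since both contrasts use the same untreated arrays. Neither number therefore tells whether these genes changed at both doses. No gene was called at both doses without untreated replicate 1, untreated replicate 2, 20 nM replicate 1 or 20 nM replicate 3, 2 were without 20 nM replicate 2 and 19 without untreated replicate 3. The genes that rose at 60 nM had a median log2 fold change of 0.08 at 20 nM against 0.62 at 60 nM, and those that fell -0.08 against -0.46, values of genes chosen by the 60 nM result, with no unchanged value simulated for them alone. Over all genes the 2 doses had the same sign for 63.9%, against 66.7% in the simulation. Across genes, which are not independent replicates, the fold changes of the 2 doses correlated at 0.563 against 0.50 in the simulation, and their covariance was 0.0234 against 0.00554. The untreated arrays were too few to split, so part of these values may come from the shared controls.

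**Figure D4:**
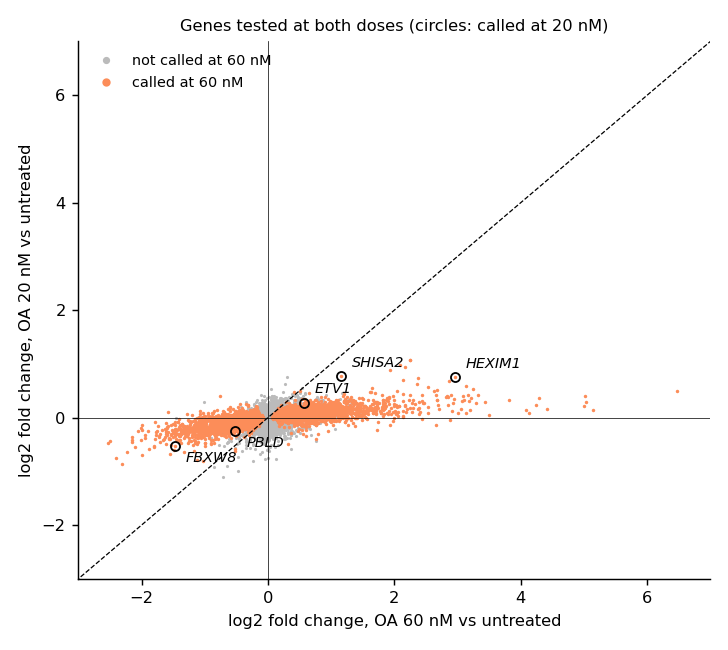
Log2 fold change against untreated cells at 60 nM OA (horizontal axis) and 20 nM OA (vertical axis) of 22465 genes (points), with genes called at 60 nM in orange, the 5 genes called at 20 nM circled and a dashed line where both are equal. ACTBL2 reaches 6.46 at 60 nM and 0.49 at 20 nM.

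Set against 20 nM OA, ACTBL2 (5.97, SE 0.36), ATP1B2 (5.00, SE 0.15), GABRQ (4.78, SE 0.13), CCDC80 (4.74, SE 0.11) and JUNB (4.61, SE 0.20) rose most at 60 nM, and these were also the 5 that rose most against untreated cells. The 20 nM means of ATP1B2 and GABRQ were at background and that of CCDC80 was 5.88, so that their folds depend on the background level. DHX32 (-2.07, SE 0.10), TMEM150C (-2.06, SE 0.06), the helicase subunit MCM3 (-1.85, SE 0.12) and PRIM1 (-1.80, SE 0.08) were among the 5 that fell most. Of the immediate early genes 22 rose and none fell, of the mitosis genes 23 rose and none fell, and of the DNA replication genes 23 fell and 3 rose. In total 4006 genes differed (1558 higher, 2448 lower), and camera called 13 lists, 9 higher and 4 lower, none with an estimated correlation (smallest adjusted p = 0.232). A shift by the hybridisation controls moved the median of all genes by -0.28 and left 562 genes higher and 2529 lower, and the chromosome score left 2291 genes. Over the 3 doses together, 4146 genes differed by limma's F test.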

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

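The comparison of noradrenergic markers with background, the tests of the few calls at 20 nM, the chromosome score and the fit outside the gene table were chosen only after the results were seen. The test of matched lists and the splits of the arrays were set before their outcomes were known.

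A signal appeared in probe sets that the comparisons did not use. Of 43747 transcript clusters with no listed symbol or several, 2120 differed between 60 nM OA and untreated cells (limma adjusted p under 0.05), 975 higher and 1145 lower, which is 4.85% against 21.2% of the named genes. Of those that rose at least 2-fold, 58 moved from background to above it. The count was 629 at 2-fold, 1038 at adjusted p under 0.01, 748 with the chromosome score, 12370 with array weights (whose estimation did not converge), 1234 without untreated replicate 2 and 1367 without 60 nM replicate 2. The real split gave 2120 and the highest of the other splits 0, and 3 against 3 arrays make 10 splits, too few for a share under 0.05 (1 of the 10 gave as many). The other splits mix the groups, so that a real difference would widen the spread and lower their counts.

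The first pattern is the fall of DNA replication genes beside the rise of mitosis genes at 60 nM. Calls at 60 nM leaned by chromosome: 14.8% of the called genes above background on chromosome 22 and 21.9% on chromosome 19 rose, against 54.7% on chromosome 13 and 56.2% on chromosome 8, and the untreated arrays differed among themselves along the same chromosome score (-0.04, 0.08 and 0.32). If a trend between arrays across chromosomes were the whole cause, lists matched on level and on each gene's slope on that score would move alike. They did not: 0% of 10000 matched random lists had a median as low as DNA replication (-0.65, against a 1st percentile of -0.36). For mitosis, 100% lay below its median (0.71, against a 99th percentile of 0.24). This cannot decide whether the trend was the whole cause, since members of the real lists vary together and genes drawn at random need not. Camera estimated correlations of 0.34 among DNA replication genes and 0.20 among mitosis genes. Their medians can thus stray farther than those of random lists, and that cause stays open. The score and the 60 nM dose go together, so the part of each shift that the score takes up cannot be assigned to either, and a change in the share of cells at each stage of the cycle stays open as an untested hypothesis.

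The second pattern is that the markers expected of SH-SY5Y were mostly at background in untreated arrays. Arrays that miss even bright transcripts are argued against, since 100% of the mitosis and DNA replication genes were above background. The untreated medians of these lists were 10.8 and 10.6, far above the level of 5.82. Low sensitivity of the arrays for dimmer transcripts therefore stays open. Above background were 24% of the noradrenergic markers (6 of 25), against 25% of epithelial markers (4 of 16) and 43.6% of all genes tested. Such values, from few markers, would go with cells other than the labelled line, or with a culture that has lost noradrenergic identity. Insensitive probe sets of these genes cannot be told apart from that, since 28% of these markers were above background in at least 1 group, untreated arrays included, and no sample is known to express the genes.

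The third pattern is the step from 5 called genes at 20 nM to 4752 at 60 nM. A wide spread of the 20 nM arrays is argued against as the whole cause, since without untreated replicate 3 and 20 nM replicate 2, which stand apart, 27 genes were called at 20 nM and 4369 at 60 nM, with the 20 nM arrays left differing by a median of 0.048 (log2) against 0.0427 to 0.0647 among the 60 nM arrays. With all arrays, 20 nM replicate 2 correlated at 0.998 with an untreated array and at 0.996 and 0.997 with those of its own group, and changes at 20 nM too small for this number of arrays stay open. An equal dose in both treated groups with no other difference, as the treatment field of the 60 nM arrays would have it, is argued against by the 4006 genes that differed between them. The dose is the biological difference that the design names, and it stays open as untested.

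Other splits of the same 6 arrays gave at most 0 genes for each contrast, where the real splits gave 4752, 5 and 4006 (1 of 10 splits each). Every other split put arrays of both groups on each side. A real difference would then widen the spread, so counts near 0 were set in advance and do not tell against chance. They gave at most 13 lists for 60 nM against untreated (real 15, 1 of 10 splits as large), 13 for 20 nM against untreated (real 11, 2 of 10) and 12 for 60 nM against 20 nM (real 13, 1 of 10). With 10 splits no share under 0.05 can be reached, and the counts of camera calls in wrong splits show how many lists the preset correlation calls in these arrays when the groups are mixed. The mixed sides held unequal numbers of arrays of each group, so these list counts may keep part of a real difference. For the F test, 5 of 100 drawn regroupings of the 9 arrays gave as many genes as the real one (4146, highest other 5225), so chance was not excluded there by the threshold of 0.05. The 4 others all kept the 60 nM arrays together. The highest count with them apart was 0, where a real difference would widen the spread as well. For genes changed at both doses in the same direction, 2 of 100 gave as many as the real 5, a share that is not read as excluding chance. Regroupings that parted the 60 nM arrays gave 0, and of the 7 others drawn that kept them together 1 gave more (3708).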

How the results depend on the processing

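The removal of genes with repeated values, of 2 arrays that stand apart (untreated replicate 3 and 20 nM replicate 2), equal array medians and the chromosome score were chosen after seeing the data. Alternatives not named here left the counts of genes and lists within 1.5 times. The removal of probe sets by ID ending was not run, since no gene's probe set has such an ID. The cause of a change was not tested, except that stricter thresholds lower counts by construction, and that the hybridisation control shift gave every gene an SE of 0.204 in place of a median of 0.0612. Fewer arrays lowered some counts and raised others: the 5 genes at 20 nM became 0 without untreated replicate 1 and 19 without untreated replicate 3.

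Genes at 60 nM against untreated numbered 4752, and 2248 after a shift by the hybridisation controls, 9185 with array weights, 769 at 2-fold, 2954 at adjusted p under 0.01 and 2533 with the chromosome score, of which 2102 were among the 4752. For 60 nM against 20 nM the 4006 became 518 at 2-fold, 2256 at 0.01 and 2291 with the score. The F test gave 10220 with array weights, 2437 at 0.01 and 1751 with the score. The estimation of the weights did not converge (58.4 for untreated replicate 2, 0.117 for 20 nM replicate 2), so counts with them are given but not relied on.

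The 5 genes at 20 nM became 17 with each probe set tested, 9 without dim genes, 17 with cyclic loess, 16 (all higher) after the hybridisation control shift, which moved the median of all genes by 0.29, 2329 with array weights, 2 with 6 arrays, 0 at 2-fold, 3 at 0.01, 27 without the 2 arrays that stand apart, 0 with equal medians and 20 with the score. Genes called at both doses were 17, 9, 17, 13, 1554, 0 at 2-fold, 3, 19, 0 and 20 under the same settings, without that of 6 arrays.

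Lists at 60 nM against untreated fell from 15 to 8 at 0.01 and to 0 with an estimated correlation, and those at 60 nM against 20 nM from 13 to 0 with it. Lists at 20 nM went from 11 to 5 with array weights, 7 at 0.01, 0 with an estimated correlation, 0 with fry and 3 without the 2 arrays that stand apart.

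Leaving out each array in turn gave 3664 to 4774 genes at 60 nM against untreated, 2824 to 4484 against 20 nM, 2827 to 4467 for the F test, 0 to 19 at 20 nM and 0 to 19 at both doses. Lists ranged from 13 to 16, from 11 to 14 and, at 20 nM, from 2 (without 20 nM replicate 2) to 12.

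With the replicate number as a block the counts were 3800 for 60 nM against untreated, 2857 against 20 nM, 0 at 20 nM and 0 at both doses. The numbers do not pair the samples: deviations of arrays of 1 number correlated at -0.519 to 0.0774 across genes.

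The ribosome biogenesis list at 20 nM turned with array weights (adjusted p = 0.882) and ranged from 0.000173 to 0.806 with each array left out, where it turned without 20 nM replicate 2. MAPT turned to -0.007 with quantile normalization and -0.008 with equal medians, PBLD and AMOTL2 at 20 nM to 0.047 and 0.127 after the hybridisation control shift, and PPP2CA and KRT18 to -0.078 and 0.05 with the score. Of the other single genes and lists, 4361 values kept direction and side of the threshold, 406 lost and 10 gained the call. Signal over background limits genes other than the 10062 above 5.82 in a group.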

Other observations

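The chromosome score was chosen after seeing the data. All lists here were fixed before the data were examined, values in parentheses after a list are camera adjusted p at 60 nM against untreated cells, and gene values are log2 fold changes. Over all genes tested 21.2% were called at 60 nM, and of 972 genes above background on chromosome 1, 152 rose and 279 fell. Counts of members near or under such shares are not read as responses of a list. Genes of autophagy and the lysosome moved in both directions at 60 nM, 5 of 31 higher and 6 lower. The autophagosome genes MAP1LC3B (11.19 ± 0.22 to 12.69 ± 0.02) and GABARAPL1 (1.36, SE 0.07) rose, while GABARAP (-0.51, SE 0.10) and the lysosomal protease gene CTSD (-0.69, SE 0.12) fell (camera adjusted p = 0.885). Of 27 apoptosis regulators 6 rose and 4 fell, with the BH3-only genes PMAIP1 (1.60, SE 0.12) and BCL2L11 (1.23, SE 0.08), BNIP3 (1.08, SE 0.04) and APAF1 (0.70, SE 0.08) higher (camera adjusted p = 0.255). Of 20 cholesterol biosynthesis genes 7 fell and 3 rose, with HSD17B7 (-1.15, SE 0.05), MSMO1 (-0.98, SE 0.11), FDPS (-0.78, SE 0.07) and the regulator SREBF2 (-0.77, SE 0.10) lower (0.0965). Of 10 metallothioneins 3 fell and 1 rose, with MT1F at -1.33 (SE 0.14), MT2A at -0.26 (SE 0.07), MT1H at -0.18 (SE 0.04) and MT1X at 0.47 (SE 0.06) (0.274). Of 28 proteasome genes 6 fell and 0 rose, led by PSMB4 (-0.65, SE 0.08) (0.0622). All 28 were above background, and the share that fell was no higher than that of such genes on chromosome 1 (279 of 972).

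Among ER chaperones 6 of 22 rose and 1 fell, with HERPUD1 at 1.51 (SE 0.13), DNAJB9 at 0.49 (SE 0.05) and DERL3, at background at 60 nM, at -0.53 (SE 0.05) (camera adjusted p = 0.349, median -0.01 and mean 0.12). Of 29 ribosome biogenesis genes 5 rose and 2 fell, with LYAR at 0.74 (SE 0.13) and POLR1B at -0.26 (SE 0.06) (0.314). Of 26 interferon response genes 3 rose and 2 fell, with IFI6 at 1.04 (SE 0.11) and OAS3 at -0.60 (SE 0.06) (0.735). Among these, 2 of the 3 that rose were at background untreated and at 60 nM. Of 26 ion channel genes of neurons 3 rose and 2 fell, and the nicotinic receptor subunit gene CHRNA5 rose by 1.40 (SE 0.11) (0.409). Here too 2 of the 3 that rose were at background untreated and at 60 nM. Of 21 neuropeptide and neurotrophin genes 3 rose and 1 fell, with GAL at 0.44 (SE 0.09) and CPE at -0.29 (SE 0.02) (0.184). The untreated means of 2 of the 3 that rose were at background. Of 27 synaptic vesicle and release genes 4 rose and 2 fell, with HOMER1 at 1.31 (SE 0.14), VAMP1 at 0.99 (SE 0.05) and VAMP2 at -0.78 (SE 0.12) (0.349). HOMER1 is counted with the list but is not taken here as a vesicle gene. The untreated means of 2 of the 4 that rose were at background. Of 22 mesenchymal type markers 5 rose and 2 fell, with CD44 at 1.04 (SE 0.06), SOX9 at 0.87 (SE 0.10) and SNAI2 at 0.81 (SE 0.08) (0.153). Of 15 leukocyte markers CD68, a lysosomal membrane protein gene, rose (1.88, SE 0.11) (0.255), of 11 Schwann and glial markers OLIG2 rose at background (0.17, SE 0.05) (0.148), and of 16 epithelial markers 0 changed (0.909), with KRT18 at -0.28 (SE 0.10, adjusted p = 0.0982). The calls of CPE, DERL3, DNAJB9, GABARAP, GAL, MT1H, MT1X, MT2A, OLIG2 and POLR1B were lost after a shift by the hybridisation controls, where each fold moved by 0.00867 and the SE of every gene became 0.204. With the chromosome score the calls of CTSD (-0.308), GABARAP (-0.17), LYAR (0.349), MT2A (-0.166), POLR1B (-0.144) and VAMP2 (-0.436) were lost with folds that shrank by over 1.5 times. Those of MT1H (-0.16), OLIG2 (0.239) and SREBF2 (-0.522) were lost with folds that did not, and KRT18 had a value of 0.05. The fit of 6 arrays ended the calls of GABARAP, GAL, MT1H, MT2A and OLIG2 (adjusted p of 0.0503 to 0.134), and quantile normalization and cyclic loess those of MT1H, MT2A and OLIG2 (0.0712 to 0.203). Without untreated replicate 2 the calls of GAL, MT1H, MT2A, OLIG2 and POLR1B were lost (adjusted p = 0.0511, 0.0527, 0.0691, 0.103 and 0.0578), and those of GAL, MT2A, OLIG2 and POLR1B also without other single arrays.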
